A study of Mus musculus with 37 samples.

How the data were processed

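Total RNA from mouse skin was profiled on Affymetrix arrays. Per the labels, RNA was extracted with Trizol, and biotinylated cRNA was prepared from 6 ug of total RNA by the manufacturer's standard protocol. The authors deposited 1 table of 31 arrays and 1 table of 6 arrays, with a value for each probe set and array. The deposited values were used as log2 signals: they run from 0.54 to 13.5 in the larger table and from 1.29 to 13.1 in the smaller. The software that summarised probes to probe sets, the array design and the genome build are not given in the sources used here. Within each table the deposited values were already quantile normalized, since 99.988% and 99.992% of the sorted values lay within 0.01 of the mean over arrays, and median levels were 4.70 and 6.14. Levels were therefore never compared between tables. A further deposited table with 10 columns that match none of the labelled samples was not used.

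Samples were grouped by their labels. The 31-array table held flaky tail (5), Flg mutation (5), C57BL/6NCrSlc ear controls (5), NC/Nga with mites (5) and without (5), OVA-ODT (3) and C57BL/6NCrSlc dorsal controls (3), and the 6-array table held OXA (3) and acetone controls (3). The labels name no batch, and a difference in processing between groups cannot be seen from them. Sex, age and site were the same within each comparison by the labels, apart from the site of flaky tail. Arrays were numbered in the order of the deposited samples, and nothing in the labels pairs arrays of different groups.

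Probe sets were named from the array annotation. The larger table had 41345 probe sets, of which 23521 carried 1 gene symbol, 1820 several and 16004 none; the smaller had 34760, with 21640, 1321 and 11799. Probe sets with exactly 1 symbol were kept, and for 1082 and 954 genes with several probe sets the one with the highest mean over all arrays stood for the gene, leaving 22180 and 19937 genes. The remaining probe sets were tested separately.

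Each comparison was fitted with limma 3.58.1 in R 4.3.3, using a mean per group over all arrays of the table and empirical Bayes moderation without trend or robust options. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all named genes, and a gene was called changed at an adjusted p under 0.05. The number of called genes with at least a 2-fold change was counted beside it. Differences between models in the larger table were tested as contrasts of effects in the same fit. With 3 to 5 arrays per group, the number of arrays limits the precision. The procedure was tested on simulated data in which 200 genes were given known changes. Changes of 0.5 on the log2 scale were recovered for 48% of genes in flaky tail, 46% with the Flg mutation, 60% in NC/Nga mice, 32% with OVA-ODT, 38% with OXA and 50% in flaky tail against the Flg mutation. Changes of 1 were recovered for 92%, 90%, 90%, 74%, 96% and 88%, changes of 2 for at least 96%, and changes of 4 for 100%, with 9, 13, 10, 8, 3 and 15 wrong calls. The simulated noise was independent between genes and arrays. These wrong calls therefore do not cover structure that the real genes or arrays share, which can give more.

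A set of 29 gene lists, holding 519 distinct genes for cytokine pathways, skin cell types, barrier, appendages and human lesions, was fixed before the data were examined, and 485 and 482 of these genes were measured. Older symbols in the annotation were matched (Il36a, Il36b and Il36g as Il1f6, Il1f8 and Il1f9, Ear11 as Rnase2a, and Krt83 as Krt87 in the smaller table). Lists were tested with limma's camera at its preset correlation of 0.01, two-sided and adjusted over the 29 lists of a comparison, again with a correlation estimated from the residuals, and with fry. Genes named in the text followed a rule also fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, up to 4 called members of each list described by absolute change, and a fixed panel of 19 genes. Symbols of Gm or RIKEN type were left out of the largest rises and falls, and statements of largest changes refer to the genes taken this way. Genes outside this rule are named where few genes of a list were called or where the text says that they were chosen later.

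Alternatives covered the groups in the fit, the variance model, array weights, a further quantile normalization, removal of the 25% of genes with the lowest mean (under log2 3.10 and 5.41), the mean of all probe sets of a gene, every probe set alone, dorsal in place of ear controls, split controls, and each array left out in turn. For a named gene whose call was lost, the array whose omission gave the highest adjusted p is given. Other omissions may end the same call, and each leaves fewer arrays. Splits of the arrays into groups of the same sizes were refitted, all of them or 100 drawn at random. Fold changes of models were correlated across genes, and the relation of list scores across 21 arrays was tested with 100000 permutations. Gene order on the mouse genome was taken from a reference annotation only to find neighbours of Flg. Correlations and figures used R and Python 3.11.15 with matplotlib 3.10.9.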

Results

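Gene expression was measured on Affymetrix arrays in skin from 5 mouse models of atopic dermatitis and from the control mice that the labels assign to each. The flaky tail mouse, a spontaneous mutant known to carry defects in Flg (filaggrin) and Tmem79, was represented by 5 arrays labelled back skin. Mice labelled with a filaggrin mutation gave 5 arrays from the ear, and 5 ear arrays of untreated C57BL/6NCrSlc mice served as controls for both, all from females of 26 weeks. NC/Nga mice, an inbred strain used as a dermatitis model, gave 5 ear arrays with mites and 5 without, from males of 10 weeks. The treatment labelled OVA-ODT was applied to C57BL/6NCrSlc females of 15 weeks, with dorsal skin taken 24 h after the last sensitization on 3 arrays and 3 arrays of untreated dorsal skin beside them. The treatment labelled OXA was applied to BALB/c females of 10 weeks, with ears taken at 2 h on 3 arrays and 3 acetone-treated ears as controls. The first 4 models lay in one table of 31 arrays with 22180 named genes, and the OXA model in a separate table of 6 arrays with 19937 named genes, so levels were compared only within a table. Replicates are separate arrays, and the labels do not say that each came from its own animal, so p-values measure the spread between these samples. Microarrays have no read depth, and the number of arrays per group limits the precision.

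The comparisons asked how each model differed from its own controls. A gene was called changed at a limma adjusted p under 0.05. By that measure 3975 genes changed in NC/Nga mice with mites, 3441 with OXA, 2617 with OVA-ODT, 1689 in flaky tail and 974 with the Flg mutation. Changes of at least 2-fold numbered 634, 586, 666, 209 and 37 in the same order. The files give no background level, so folds of genes whose lower group mean lay among the dimmest 25% of genes are uncertain. Of the called genes chosen for naming this applied to 4 in flaky tail (Il17a, Tyr, Mrgpra9 and Rnase2a), none with the Flg mutation, 10 in NC/Nga mice, 6 with OVA-ODT, 23 with OXA and 4 in flaky tail against the Flg mutation. Several of the largest folds given below are among them. In NC/Nga mice they included Stfa2l1, S100a7l2, Cxcl5, Cxcl3 and Chil3, and with OVA-ODT Olah, Serpinb3a, Ifng and Fcer1a. With OXA they included Krt6b, Chil4, Stfa2, Iigp1, Scgb1a1, Ifit1, Il19, Il6, Ifng, Gzmb and Gzma.

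**Figure D1:**
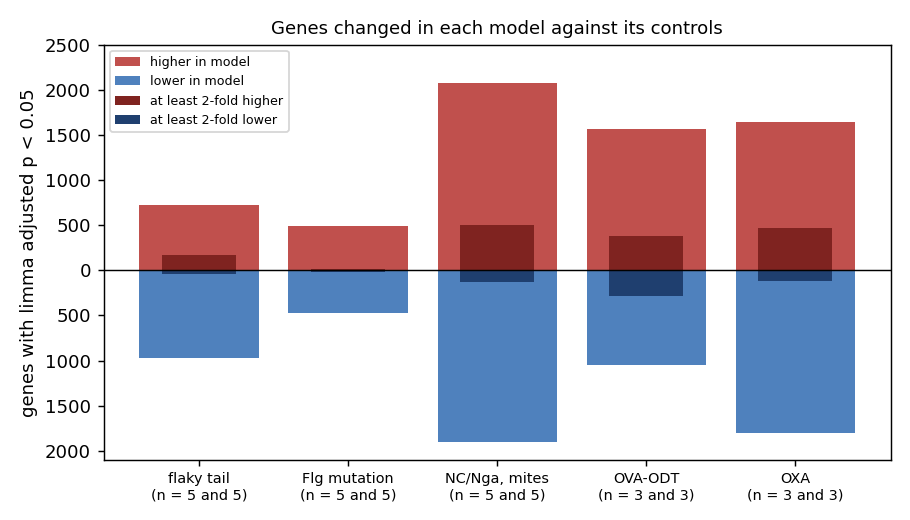
Number of genes past the limma threshold in each model against its controls, with genes higher in the model above 0 and genes lower below it. Wide bars give all changed genes and narrow dark bars those changed at least 2-fold, and the Flg mutation had the fewest at 37.

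Flaky tail skin against ear controls showed higher antimicrobial, hair follicle and Th17 transcripts. S100a8 and S100a9, subunits of the antimicrobial protein calprotectin, were 17.8-fold higher (log2 change 4.16 ± 0.48, SE, n = 5 and 5) and 10.4-fold higher (3.38 ± 0.42). Stfa3, a stefin-type protease inhibitor, rose 14.5-fold (3.86 ± 0.33), and Serpinb3a rose 8.66-fold (3.11 ± 0.35). Il17f, a cytokine of Th17 cells, rose 4.26-fold (2.09 ± 0.18), while the type 2 cytokine transcripts Il4 and Il13 differed by 0.04 ± 0.15 and -0.10 ± 0.20 on the log2 scale and did not pass. Il4 was dim, at 2.57 in ear controls, so a change there could be missed. Among 22180 genes 720 rose and 969 fell, and 169 and 40 of them did so at least 2-fold. The values of both groups were fully apart for 6.10% of genes, where chance gives 0.794%.

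Flg itself was 1.49-fold lower in flaky tail (log2 change -0.57 ± 0.16, adjusted p = 0.025), at 9.41 ± 0.43 (SD) against 9.98 ± 0.23. Tmem79, whose loss is the second known flaky tail defect, was 1.54-fold lower (-0.62 ± 0.11), and Lor, the main protein of the cornified envelope, 1.65-fold lower (-0.73 ± 0.12). Where the mutations lie relative to the probe sets is not given in the sources used here, so these values do not check the genotype. Of 37 measured genes for the cornified envelope and terminal differentiation 6 rose, 12 fell and 19 did not pass (7 and 16 adjusted over the list alone). Rptn (repetin) rose 3.56-fold and the suprabasal keratin Krt1 2.22-fold, against the falls in Lor and Flg. The list as a whole leaned downward (camera adjusted p = 0.0403; adjusted p = 0.525 with an estimated correlation), with a median log2 change of -0.24 and a mean of -0.03. Tight junction genes gave 1 rise and 3 falls among 16, led by Cgn (cingulin, -0.88 ± 0.16), and that list did not pass. Among 29 barrier lipid genes 6 rose and 4 fell, with Degs2, a ceramide-modifying enzyme, at 1.05 ± 0.17. The epidermal lipoxygenases Aloxe3 and Alox12b fell (-0.98 ± 0.14 and -0.55 ± 0.10), and the list did not pass.

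Of 22 genes of the IL-22, antimicrobial and hyperplasia list 10 rose and none fell (14 and 0 adjusted over the list alone), with a median log2 change of 1.23 (camera adjusted p = 1.94e-13; adjusted p = 0.120 with an estimated correlation). Saa3 (serum amyloid A), Lcn2 (lipocalin) and the defensin Defb3 were among them. The hyperplasia keratins Krt6a and Krt16 were higher by 0.90 ± 0.35 and 1.32 ± 0.43 without passing, at adjusted p = 0.12 and 0.057. The list of Th17 and neutrophil-recruiting cytokines had 5 rises among 21 (6 adjusted over the list alone). These were Il17f, the IL-23 receptor Il23r at 3.60-fold, Il20 at 3.05-fold, Il1f6 (an IL-36 cytokine) at 2.68-fold and Il17a at 2.16-fold from a dim control level of 2.19 (camera adjusted p = 4.43e-06; adjusted p = 0.156 with an estimated correlation). Il22 itself was at 1.17 ± 0.09 against 1.16 ± 0.12 (SD), a dim level at which a change could be missed. The Th2 list had no rise and 2 falls among 22, Gata3 and Tnfrsf4. The Th1 and interferon list had no change among 23, and neither passed as a list.

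Both hair follicle and melanocyte genes rose in flaky tail. Of 26 hair keratins and regulators 18 rose and none fell (24 adjusted over the list alone), with a median log2 change of 2.18 (camera adjusted p = 1.53e-20; adjusted p = 0.191 with an estimated correlation). Krt84 rose 10.3-fold (3.37 ± 0.48) and the inner root sheath keratins Krt72 and Krt28 9.88-fold and 8.95-fold. Of melanocyte genes 7 of 10 rose (8 adjusted over the list alone). They included the pigment enzymes Tyr (1.66 ± 0.33), Tyrp1 (1.42 ± 0.22) and Dct (1.02 ± 0.20), with camera adjusted p = 1.16e-08 and adjusted p = 0.128 with an estimated correlation. Sebaceous gland genes gave 6 rises and 2 falls among 16 (8 and 3 adjusted over the list alone). They included the wax and lipid enzymes Elovl3 at 2.83-fold, Awat1 at 2.76-fold and the desaturase Scd3 at -1.24 ± 0.27 (camera adjusted p = 0.000121; adjusted p = 0.229 with an estimated correlation). Of 22 proliferation genes 6 rose (11 adjusted over the list alone), such as Tpx2 (0.67 ± 0.15) and the replication factor Mcm6 (0.45 ± 0.11), with camera adjusted p = 1.38e-08 and adjusted p = 0.228 with an estimated correlation.

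Immune cell markers changed little in flaky tail. No neutrophil gene passed among 18, none among 6 eosinophil genes and none among 7 basophil genes. Mast cells had 1 fall (Mrgprb2), T cells 1 rise (Icos) and 1 fall (Trat1), and dendritic cells 1 fall (Flt3). Macrophages had 1 fall (Cd68), alternatively activated macrophages 1 fall (Rnase2a), NK cells 1 fall (Klrd1) and B cells 1 rise, the kinase gene Blk (1.88 ± 0.29). Markers of other tissues gave no muscle or trunk Hox call, 1 cartilage fall (Acan), 1 adipocyte rise (Lpl) and 1 collagen-list fall (Eln). The immediate early list had 1 rise (Atf3) and 1 fall (Klf4). None of these 16 lists passed as a list. Of 31 genes known to be raised in human atopic dermatitis lesions 5 rose and 1 fell, Tnfrsf4 (12 and 1 adjusted over the list alone; camera adjusted p = 8.97e-05; adjusted p = 0.238 with an estimated correlation). Of 25 known to be lowered in lesions 7 rose, led by Fabp7 (2.14 ± 0.20), and 4 fell, so the list leaned upward (8 and 5 adjusted over the list alone; camera adjusted p = 0.0489; adjusted p = 0.381 with an estimated correlation). Among called genes whose groups did not overlap, those that fell furthest were Pisd-ps3 (4.94-fold), the progestin receptor gene Paqr7 (4.82-fold), Tgm7 (4.00-fold), Mrgpra9 and Pls1 (3.38-fold each) and Olfr466 (3.33-fold).

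Fitting the flaky tail and ear control arrays alone gave 814 changed genes in place of 1689, and using dorsal controls in place of ear controls gave 5327. The rises of Tpx2 and Mcm6 and the falls of Flg, Tnfrsf4, Trat1, Flt3, Cd68 and Klf4 no longer passed with the 2 groups alone. Calls of Flg (adjusted p = 0.0900 without flaky tail array 4), Rnase2a (0.0800 without ear control 3), Eln (0.0599 without ear control 4), Atf3 (0.111 without flaky tail array 3) and Klf4 (0.0942 without flaky tail array 2) were lost on leaving out a single array. The cornified envelope list no longer passed without flaky tail array 2, 3, 4 or 5 or ear control 1 or 3 (camera adjusted p up to 0.0870), nor did the list of genes lowered in lesions without flaky tail array 2 or 5 or ear control 1, 2 or 3 (up to 0.124). Proliferation rises fell from 6 to 3 without flaky tail array 2 or ear control 1, and tight junction falls from 3 to 1 without ear control 5.

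The site labels of this comparison differ, back skin for flaky tail and ear for its controls, so the arrays were placed between the dorsal and ear controls of the same table. Dorsal and ear controls differed for 5165 genes, and 443 of these did so at least 4-fold. On a scale from 0 at the ear controls to 1 at the dorsal controls, the flaky tail mean had a median position of 0.123 over these genes (quartiles 0.027 and 0.423), and the OVA-ODT mean, labelled dorsal, 0.644. Hoxc6, a gene of trunk position, was at 3.69 ± 0.14 (SD, n = 5) in flaky tail, 3.35 ± 0.30 in ear controls and 6.99 ± 0.38 (n = 3) in dorsal controls. The cartilage gene Acan was at 8.45 ± 0.21, 9.36 ± 0.15 and 3.41 ± 0.16 in the same order. Some hair and pigment genes, which also separate dorsal from ear skin, lay nearer the dorsal level, with Krt71 at 10.4 ± 0.82, 7.46 ± 1.54 and 11.8 ± 0.30 and Tyrp1 at 7.26 ± 0.50, 5.84 ± 0.21 and 8.04 ± 0.50. These genes were chosen after their values were seen.

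**Figure D2:**
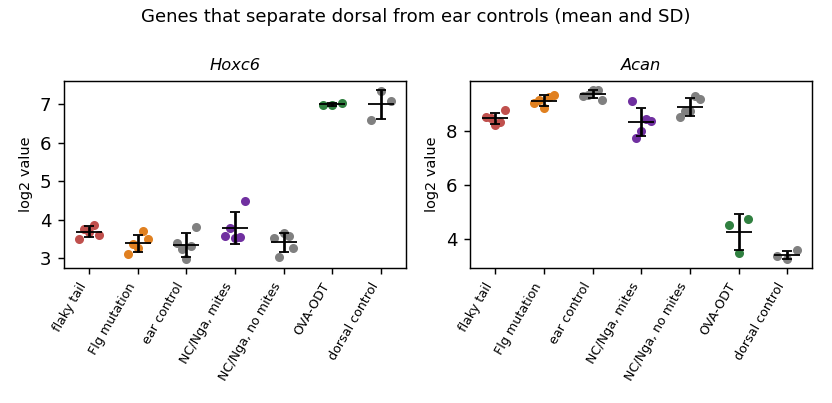
Log2 value of Hoxc6 and Acan on each array of the 31-array table, by group, with points for arrays and bars for the mean and SD. Flaky tail arrays, labelled back skin, had Hoxc6 at 3.69 ± 0.14, where dorsal controls had 6.99 ± 0.38.

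The Flg mutation lowered Flg most clearly among the fixed panel. Flg was 2.92-fold lower than in ear controls (log2 change -1.54 ± 0.16, SE, n = 5 and 5), at 8.44 ± 0.18 (SD) against 9.98 ± 0.23. Lce1g, a late cornified envelope gene, fell 3.03-fold (-1.60 ± 0.25), Abhd12b 2.84-fold (-1.51 ± 0.23) and the stress-response gene Ddit4 2.71-fold (-1.44 ± 0.18). The largest rises were Scd3, a sebaceous desaturase, at 2.86-fold (1.52 ± 0.27), the interferon-induced GTPase Gbp7 at 2.60-fold (1.38 ± 0.29), Vsnl1 at 2.49-fold, Tmem47 and Lgals12 at 2.31-fold each and Dhdh at 2.25-fold. The other probe set of Tmem47 changed by 0.39 on the log2 scale. In total 496 genes rose and 478 fell, and 20 and 17 of them did so at least 2-fold. The groups were fully apart for 6.94% of genes, where chance gives 0.794%.

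The fall in cornified envelope genes took in 8 of 37 members and no member rose (1 rose and 11 fell adjusted over the list alone), with camera adjusted p = 2.88e-05 and adjusted p = 0.220 with an estimated correlation. Besides Flg these included Lce1f (2.15-fold lower), Lce3c (1.99-fold) and Lor (1.52-fold). Among barrier lipid genes Alox12b (-0.58 ± 0.10), the ceramide-synthesis gene Pnpla1 (-0.55 ± 0.11, its other probe set -0.10) and Cers3 fell and Elovl6 (0.88 ± 0.17) and Fads1 rose. That list of 29 did not pass. Sebaceous gland genes gave 4 rises among 16, Scd3, Thrsp, Elovl5 and the lipid regulator Pparg at 0.76 ± 0.12 (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.85e-06; adjusted p = 0.220 with an estimated correlation). Adipocyte genes gave 3 rises among 13, Retn (resistin, 1.00 ± 0.22), Adipoq (adiponectin) and Lpl (camera adjusted p = 0.00318). The skeletal muscle list leaned upward without a passing member (median 0.35, camera adjusted p = 0.0156), and both of these had adjusted p = 0.808 with an estimated correlation.

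Some antimicrobial and IL-36 genes were lower with the Flg mutation. Of 22 IL-22, antimicrobial and hyperplasia genes 2 fell, Stfa3 (-1.27 ± 0.33) and the defensin Defb14 (-0.79 ± 0.16), and none rose (7 fell adjusted over the list alone; camera adjusted p = 0.00318; adjusted p = 0.808 with an estimated correlation). S100a8 and S100a9 differed by -0.73 ± 0.48 and -0.85 ± 0.42 and did not pass. The IL-36 cytokines Il1f6 and Il1f8 fell by 0.82 and 0.68 on the log2 scale, the only 2 calls among 21 Th17 genes, and Il17a was at 2.09 ± 0.16 against 2.19 ± 0.32 (SD). No gene of the Th2 list passed, with Il33 at 0.45 ± 0.22 and Il4 at 0.21 ± 0.15. The Th1 and interferon list leaned upward with no passing member (camera adjusted p = 0.0207). Proliferation genes leaned downward with none (0.00415), and hair follicle genes leaned upward with none (median 0.69, 0.00318), each at adjusted p = 0.808 with an estimated correlation. No member passed among the markers of neutrophils, mast cells, eosinophils, basophils, T cells, dendritic cells, macrophages of either list, B cells, NK cells and melanocytes, nor among collagen and trunk Hox genes. Cartilage had 1 rise (Cnmd), tight junctions 1 fall (Tjp3) and the immediate early list 2 falls (Klf4 and Myc). Genes lowered in human lesions gave 5 rises, such as Acox2 (0.72 ± 0.15), and 2 falls, Flg and Lor, among 25 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00415; adjusted p = 0.306 with an estimated correlation), and no gene of the raised list passed.

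The count of 974 fell to 420 with the 2 groups alone, to 437 without ear control 2, 450 without Flg mutation array 4, 496 without array 5, 526 without ear control 5 and 593 without array 2. It rose to 1550 with array weights. Calls of Stfa3, Il1f6, Il1f8, Tjp3, Cnmd, Elovl5 (adjusted p = 0.102, 0.101, 0.0928, 0.0869, 0.124 and 0.0650 without ear control 2), Fads1 (0.0676 without ear control 1), Thrsp and Adipoq (0.0921 and 0.0692 without array 4) and Myc (0.102 without array 2) were lost on leaving out a single array. The lists of interferon, muscle and adipocyte genes no longer passed without Flg mutation array 4 (camera adjusted p = 0.467, 0.0811 and 0.0783), nor did hair follicle genes without array 3 or 4 or ear control 3 (0.388, 0.0811 and 0.0622). Sebaceous rises fell from 4 to 2 without array 3, 4 or 5, and rises among genes lowered in lesions ranged from 1 to 4 when single arrays were left out. The calls of Gbp7, Stfa3, Il1f6, Il1f8, Tjp3, Fads1, Cnmd and Myc were lost with the 2 groups alone.

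**Figure D3:**
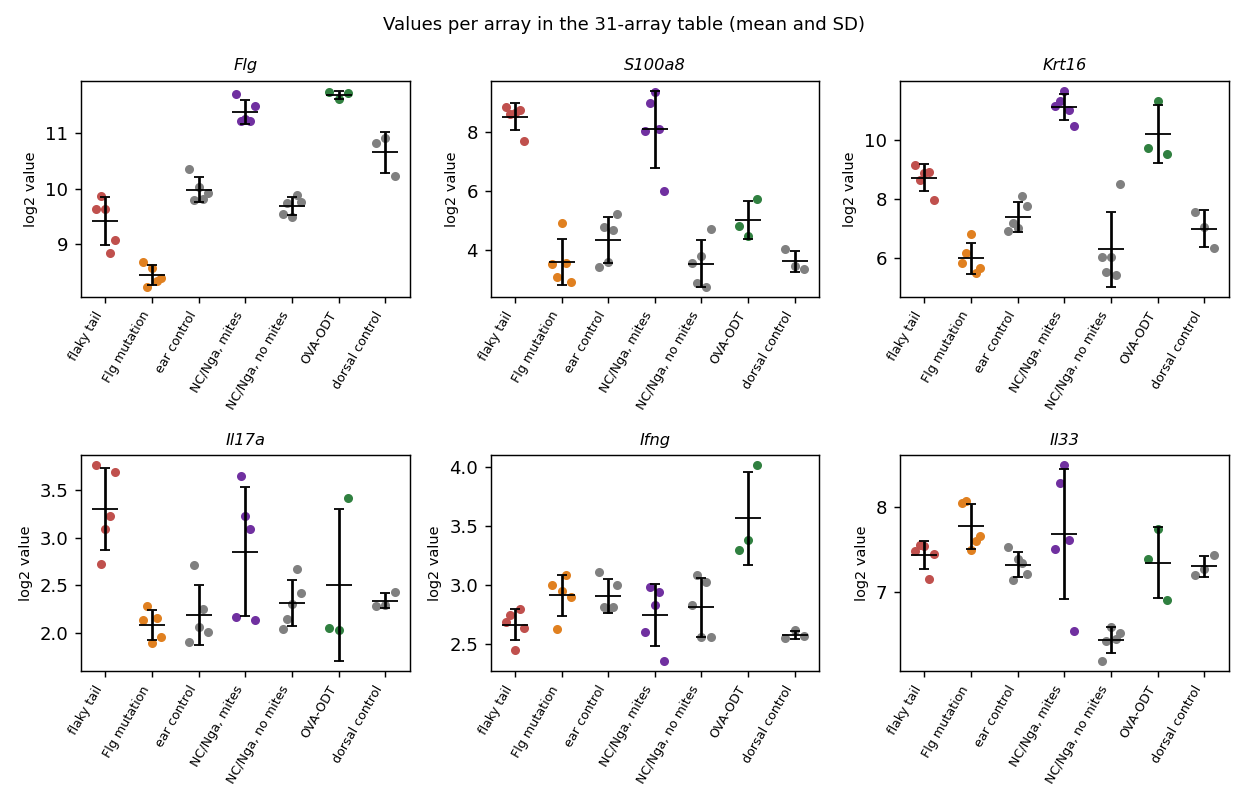
Log2 value of 6 panel genes on each array of the 31-array table, by group, with points for arrays and bars for the mean and SD. Flg was lowest with the Flg mutation (8.44 ± 0.18) and S100a8 was high in flaky tail (8.49 ± 0.46) and in NC/Nga mice with mites (8.07 ± 1.30).

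The direct comparison of flaky tail with the Flg mutation, made without controls, asked whether the 2 filaggrin-related models differ. The site labels differ here too, back skin for flaky tail and ear for the Flg mutation. Most site genes of flaky tail lay near the ear level, but some hair and pigment genes lay nearer the dorsal level. Differences in those genes can therefore not be tied to the models alone. Stfa3 was 34.9-fold higher in flaky tail (log2 difference 5.12 ± 0.33, SE, n = 5 and 5), S100a8 29.5-fold (4.88 ± 0.48), S100a9 18.8-fold (4.23 ± 0.42) and Serpinb3a 12.2-fold (3.61 ± 0.35). Flg was 1.96-fold higher in flaky tail than with the Flg mutation (0.97 ± 0.16). Scd3 was 6.78-fold lower in flaky tail (-2.76 ± 0.27) and Paqr7 6.69-fold lower (-2.74 ± 0.22). In all 680 genes were higher and 879 lower in flaky tail, 121 and 37 of them at least 2-fold, and the groups were fully apart for 8.30% of genes, where chance gives 0.794%.

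Of the 29 lists 3 passed in this comparison with both the preset and an estimated correlation. The IL-22, antimicrobial and hyperplasia list was higher in flaky tail, with 14 of 22 genes passing (16 adjusted over the list alone), Krt16 among them at 2.72 ± 0.43 (adjusted p = 0.0141 with an estimated correlation). Th17 genes were higher for 7 of 21 (8 adjusted over the list alone), including Il17f (4.76-fold), Il1f6 (4.75-fold) and Il17a (2.31-fold). Proliferation genes were higher for 15 of 22 (20 adjusted over the list alone), including the mitotic kinase gene Cdk1 (0.82 ± 0.20) and Birc5 (0.76 ± 0.15), and both of these lists had adjusted p = 0.0421 with an estimated correlation. The other 10 lists that passed, from hair follicle and melanocyte genes, higher in flaky tail, to muscle and adipocyte genes, lower, did so only with the preset correlation, at adjusted p from 0.146 to 0.550 with an estimated one. Those of interferon, barrier lipid, cartilage, adipocyte and trunk Hox genes also no longer passed without some single array (camera adjusted p up to 0.416). Hair follicle genes were higher for 5 of 26 (17 adjusted over the list alone), led by Krt84 (7.48-fold), and melanocyte genes for 5 of 10, including Pmel (1.15 ± 0.24). The count of 1559 fell to 906 without flaky tail array 4, 945 without Flg mutation array 2 and 829 without Flg mutation array 5. With single arrays left out, hair follicle rises ranged from 1 to 17, melanocyte rises from 3 to 6 and proliferation rises from 9 to 14. Falls ranged from 3 to 4 for cornified envelope genes, 1 to 3 for barrier lipid genes, 2 to 5 for sebaceous genes and 0 to 4 for cartilage genes.

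Log2 changes in flaky tail and the Flg mutation were correlated across genes (Pearson 0.417, Spearman 0.432), but both were taken against the same 5 ear controls. Unchanged groups simulated against shared controls gave a mean Pearson of 0.496 (range 0.240 to 0.761), and splitting the controls between the comparisons gave 0.174 (-0.079 to 0.302). The covariance was 0.0314, against a mean of 0.0153 and a highest value of 0.0344 in the simulation. Calls in both models numbered 95 rises, 206 falls and 16 of opposite direction, where independent lists of these lengths would share 16.1, 20.9 and 37.2, and these counts rest on the same shared controls. Genes are not independent replicates in these correlations.

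NC/Nga mice with mites had the most genes past the threshold, led by epidermal hyperplasia and acute inflammatory genes, although OVA-ODT had more changes of at least 2-fold. Krt6b, a keratin of activated epidermis, rose 69.2-fold over mice without mites (log2 change 6.11 ± 0.61, SE, n = 5 and 5), Saa3 54.2-fold (5.76 ± 0.53), and the neutrophil stefin Stfa2l1 35.2-fold (5.14 ± 0.44). The pore-former gene Gsdmc rose 30.1-fold (4.91 ± 0.41), Stfa3 29.5-fold (4.88 ± 0.33) and Krt16 28.4-fold (4.83 ± 0.43). Il1b, an inflammatory cytokine, rose 25.9-fold (4.69 ± 0.55). The largest falls were S100a7l2 at 6.44-fold, Inmt at 5.27-fold, the mast cell receptor gene Mrgprb3 at 5.14-fold, Mylk4 at 3.83-fold, Nnat at 3.56-fold (its other probe set changed by 0.18 on the log2 scale) and Paqr7 at 3.46-fold. In total 2075 genes rose and 1900 fell, 506 and 128 of them at least 2-fold. The groups were fully apart for 15.7% of genes, where chance gives 0.794%.

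Of 22 IL-22, antimicrobial and hyperplasia genes 19 rose and none fell (19 adjusted over the list alone), with a median log2 change of 2.95 (adjusted p = 0.00318 with an estimated correlation). Th17 and neutrophil-recruiting cytokines rose in 13 of 21 (13 adjusted over the list alone; 0.00533), including the chemokines Cxcl2 (21.6-fold), Cxcl5 (19.8-fold) and Cxcl3 (14.6-fold). Il17a was higher by 0.54 ± 0.26 and Il22 by 0.00 ± 0.11 without passing. Neutrophil markers rose in 11 of 18 and 1 fell, Mpo (12 and 1 adjusted over the list alone; 0.0309), among the rises Clec4e (21.1-fold), Trem1 (15.3-fold) and Retnlg (13.4-fold). Macrophage markers rose in 15 of 16 (15 adjusted over the list alone; 0.0214), including Cd14 (8.18-fold) and the beta-glucan receptor Clec7a (6.42-fold), and alternatively activated macrophage genes in 4 of 11 (4; 0.0374), Chil3 (16.9-fold), Arg1, Mrc1 and Socs2. Collagen and matrix genes rose in 15 of 19 (16; 0.00935), with the protease inhibitor Timp1 at 11.1-fold and tenascin Tnc at 7.77-fold. Proliferation genes rose in 20 of 22 (21; 0.00739), such as Kif11 (2.78-fold), Bub1 (2.70-fold) and Cdk1 (2.66-fold). Genes raised in human lesions rose in 23 of 31 and 1 fell, Kynu (24 and 1; 0.00318). Tight junction genes fell in 9 of 16 (9; 0.0307), including Cgn (2.89-fold), Marveld2 (2.00-fold), Cldn8 (1.91-fold) and Ocln (occludin, 1.71-fold). Each value in these brackets is the count adjusted over the list alone and the adjusted p with an estimated correlation, and all 9 lists also passed with the preset one.

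Type 2 genes rose in part. Of 22 members 8 rose and 2 fell, Ccl24 and Gata3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00548; adjusted p = 0.0638 with an estimated correlation). The chemokine Ccl8 rose 5.32-fold (2.41 ± 0.25), the receptor gene Il4ra 3.27-fold (1.71 ± 0.23), the alarmin Il33 2.38-fold (1.25 ± 0.22), Ccl17 1.92-fold (0.94 ± 0.31) and Tslp 1.79-fold (0.84 ± 0.20). Il4 and Il13 differed by 0.24 ± 0.15 and 0.04 ± 0.20 without passing. Mast cell genes gave 8 rises and 1 fall, Mrgprb2, among 14 (9 and 1), with Hdc, the histamine-forming enzyme, at 8.42-fold (camera adjusted p = 5.88e-06; adjusted p = 0.0638 with an estimated correlation). Basophil genes gave 2 rises among 7, Fcer1a, which the mast cell list also holds, and Mcpt8 (camera adjusted p = 0.0215; adjusted p = 0.0638 with an estimated correlation). T cell genes gave 8 rises, such as Cd4 (1.27 ± 0.27) and Il2ra (1.16 ± 0.18), and 3 falls, Cd3g, Cd3e and Trat1, among 17 (8 and 3; camera adjusted p = 0.00436; adjusted p = 0.130 with an estimated correlation). Interferon genes gave 7 rises among 23 (9 rises and 1 fall), such as Oasl2 (1.19 ± 0.32) and Oas2 (1.08 ± 0.23), with Ifng at -0.07 ± 0.13 (camera adjusted p = 0.00216; adjusted p = 0.224 with an estimated correlation).

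In contrast to both filaggrin-related models, Flg was 3.25-fold higher in NC/Nga mice with mites (1.70 ± 0.16). Cornified envelope genes gave 13 rises and 5 falls among 37 (15 and 6 adjusted over the list alone), with the small proline-rich gene Sprr1b at 25.6-fold and Rptn at 23.9-fold against falls in Krt77, Lce1m, Flg2, Krt80 and Ppl (camera adjusted p = 9.50e-05; adjusted p = 0.0638 with an estimated correlation). Barrier lipid genes split into 7 rises, led by Degs2 (1.13 ± 0.17), and 7 falls, led by Elovl6 (-0.82 ± 0.17), and did not pass as a list. Sebaceous genes fell in 6 of 16 (6), led by the melanocortin receptor Mc5r at 2.12-fold (camera adjusted p = 0.00548; adjusted p = 0.238 with an estimated correlation). Muscle genes fell in 12 of 22 (17), such as Tcap at 3.14-fold, and adipocyte genes in 7 of 13 (9), such as leptin (Lep) at 2.73-fold. These had camera adjusted p = 2.74e-08 and 6.33e-05 and adjusted p = 0.219 and 0.154 with an estimated correlation. Cartilage genes fell in 2 of 15, Chad and Snorc (5 adjusted over the list alone; camera adjusted p = 0.0480; adjusted p = 0.307 with an estimated correlation). Genes lowered in human lesions gave 11 falls, such as Krt77 and the growth factor Btc (2.27-fold and 2.14-fold), and 3 rises, Flg, Fabp7 and Fads2 (3 rises and 12 falls; camera adjusted p = 0.00370; adjusted p = 0.0862 with an estimated correlation). No hair follicle gene passed among 26, and eosinophils had 1 rise (Siglecf). Dendritic cells had 3 (Fscn1, Cd80 and Ccr7), B cells 1 (Blk), melanocytes 1 fall (Mlana) and trunk Hox genes 1 fall (Hoxa5). NK cells had 2 rises (Gzmb and Gzmc) and 2 falls (Klrd1 and Nkg7), and immediate early genes 4 rises, led by Nr4a3 (1.86 ± 0.27), and 2 falls (Jun and Egr3). None of these passed as a list. Calls of Ccl17 (adjusted p = 0.0782 without NC/Nga array 2 without mites), Mcpt8 (0.0565) and Nkg7 (0.107, both without array 2 with mites), Snorc (0.116) and Mlana (0.104, both without array 3 with mites) were lost on leaving out a single array. So were those of Gzmc (0.146 without array 4 without mites), Blk (0.0791 without array 5 with mites) and Hoxa5 (0.0883 without array 2 without mites). The cartilage list no longer passed without mite arrays 2 to 5 or no-mite arrays 4 or 5 (camera adjusted p up to 0.193). With single arrays left out, rises of interferon genes ranged from 3 to 8 and of immediate early genes from 2 to 4. Falls ranged from 3 to 9 for barrier lipid genes, 3 to 6 for sebaceous genes, 6 to 13 for muscle genes and 3 to 8 for adipocyte genes, lowest without mite array 2 or 3 or no-mite array 4.

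OVA-ODT skin showed higher epidermal activation genes and lower hair shaft genes than untreated dorsal skin. Krt6b rose 28.2-fold (log2 change 4.82 ± 0.79, SE, n = 3 and 3), Stfa3 26.5-fold (4.73 ± 0.43), Olah, a fatty acid thioesterase gene, 20.9-fold (4.39 ± 0.33), Gsdmc 20.5-fold (4.36 ± 0.53), Igfl3 17.3-fold (4.11 ± 0.28) and Serpinb3a 17.0-fold (4.08 ± 0.45). The largest falls were all keratin-associated proteins of the hair shaft, among them Krtap19-1 at 35.4-fold (-5.15 ± 1.11), Krtap6-3 at 32.5-fold (-5.02 ± 0.82), Krtap31-2 at 31.3-fold and Krtap9-5 at 30.0-fold. In total 1570 genes rose and 1047 fell, 376 and 290 of them at least 2-fold. The groups were fully apart for 29.0% of genes, where chance gives 10%.

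Hair follicle genes fell in 17 of 26 (22 adjusted over the list alone), with a median log2 change of -2.25, and included Krt33b (17.4-fold), Krt83 (12.8-fold) and Krt81 (12.0-fold), at camera adjusted p = 1.85e-16 and adjusted p = 0.107 with an estimated correlation. Melanocyte genes fell in 6 of 10 (8), led by Mlana at 3.36-fold (camera adjusted p = 8.97e-07; adjusted p = 0.0801 with an estimated correlation). Muscle genes were higher for 7 of 22 (16), such as Myh1 (2.30 ± 0.45), largely on array 3, since the median of 1.24 fell to 0.19 with 1 call without it (camera adjusted p = 0.203). Leaving out dorsal control 1 gave 1 muscle call, dorsal control 2 gave 4 and array 1 gave 18. Adipocyte genes were higher genes for 4 of 13 (6), such as Lpl (1.73 ± 0.16), for 2 without OVA-ODT array 2 or 3 or dorsal control 2, and for 7 without array 1. With all arrays these lists had camera adjusted p = 9.43e-07 and 0.00251 and adjusted p = 0.267 for both with an estimated correlation. Sebaceous genes gave 9 rises and 1 fall, Scd3, among 16 (9 and 2), including Elovl3 at 4.12-fold (camera adjusted p = 4.90e-06; adjusted p = 0.0801 with an estimated correlation).

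Mast cell genes rose in 8 of 14 and 1 fell, Mrgprb2 (9 and 1 adjusted over the list alone). The carboxypeptidase Cpa3 rose 5.98-fold (2.58 ± 0.32), the IgE receptor chains Ms4a2 and Fcer1a 5.17-fold and 4.56-fold, and Mrgprb1 4.56-fold (camera adjusted p = 2.91e-10; adjusted p = 0.0503 with an estimated correlation). The 2 basophil genes that rose, Ms4a2 and Fcer1a, are both on the mast cell list (camera adjusted p = 0.00251; adjusted p = 0.0526 with an estimated correlation). Macrophage genes rose in 5 of 16 (9), such as Ms4a7 at 2.73-fold (camera adjusted p = 4.59e-05; adjusted p = 0.217 with an estimated correlation). Of 11 alternatively activated macrophage genes 4 rose, including Mrc1 at 3.77-fold, and 1 fell, Arg1 (6 and 1; camera adjusted p = 0.00433; adjusted p = 0.0810 with an estimated correlation). The neutrophil list had 2 rises, Stfa2l1 and Cxcr2, and 1 fall, Il1r2, and did not pass. S100a8 and S100a9 were higher by 1.40 ± 0.62 and 1.37 ± 0.54 without passing. T cells had 2 rises (Cd8a and Il7r) and 1 fall (Ctla4), NK cells 2 rises (Gzmc and Klrk1), dendritic cells 1 rise (Cd80) and cartilage 1 rise (Acan). Eosinophil, B cell and immediate early genes had no call. None of these passed as a list.

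Of the cytokine lists, Th17 and neutrophil-recruiting genes gave 4 rises among 21 (4 rises and 1 fall adjusted over the list alone). These were Il20 at 15.6-fold and the IL-36 cytokines Il1f6, Il1f8 and Il1f9 at 12.6-fold, 4.43-fold and 2.52-fold (camera adjusted p = 0.000588; adjusted p = 0.141 with an estimated correlation). Th1 and interferon genes gave 5 rises among 23 (6), including Ifng itself at 1.98-fold (0.99 ± 0.17) and the chemokine Cxcl9 at 3.55-fold (camera adjusted p = 0.00319; adjusted p = 0.254 with an estimated correlation). The Th2 list gave 2 rises (Il13ra2 and Ccl11) and 3 falls (Ccr4, Il31ra and Gata3) among 22 and did not pass, with Il4 at -0.07 ± 0.19 and Il13 at 0.49 ± 0.26. IL-22, antimicrobial and hyperplasia genes rose in 8 of 22 (9), with Krt16 at 9.25-fold (camera adjusted p = 1.17e-07; adjusted p = 0.0829 with an estimated correlation).

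Flg was 2.05-fold higher with OVA-ODT (1.04 ± 0.21). Cornified envelope genes gave 10 rises, such as Sprr1b (6.53-fold) and Rptn (5.73-fold), and 2 falls, Lce1m and Krt80, among 37 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00356; adjusted p = 0.179 with an estimated correlation). Barrier lipid genes rose in 12 of 29 and 1 fell, Elovl1 (16 and 1), with Degs2 at 5.35-fold, the sterol enzyme Lss at 2.69-fold and Fa2h at 2.42-fold (camera adjusted p = 1.24e-09; adjusted p = 0.0503 with an estimated correlation). Tight junction genes fell in 6 of 16 (8), such as Cldn23 and Cldn3 (camera adjusted p = 5.70e-06), and collagen and matrix genes rose in 8 of 19 (14), such as Col6a3 (camera adjusted p = 4.80e-10). Proliferation genes rose in 14 of 22 (20), such as Mcm3 (camera adjusted p = 3.73e-12), and genes raised in human lesions in 10 of 31 (12; camera adjusted p = 8.77e-08). Each of these 4 lists had adjusted p = 0.0673 with an estimated correlation. The trunk Hox list had 2 rises among 21, Hoxb7 and Hoxa6 (camera adjusted p = 0.0131; adjusted p = 0.107 with an estimated correlation), and the list of genes lowered in human lesions 8 rises and 5 falls among 25 without passing.

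With the 2 groups alone 1238 genes changed, 1743 did without dorsal control 1 and 1689 without OVA-ODT array 3, the array with the most muscle signal. Calls lost on leaving out a single array were those of Cxcl9 (adjusted p = 0.20) and Arg1 (0.118) without OVA-ODT array 1, Ctla4 (0.0665) without array 1, Cd8a and Il7r (0.0805 and 0.0915) without array 2, and Il13ra2 (0.0519) and Acan (0.239) without array 3. The same held for Il31ra and Klrk1 (0.212 and 0.0621 without dorsal control 3) and Cd80 and Hoxa6 (0.0855 and 0.0541 without dorsal control 1). Myh1, Ccl11, Hoxb7, Hoxa6, Cd8a, Klrk1, Acan and Il31ra did not pass with the 2 groups alone. The cornified envelope list no longer passed without array 1 (camera adjusted p = 0.0548), nor the trunk Hox list without dorsal control 1 (0.0625). Several counts of called list members also moved on leaving out single arrays. Interferon rises fell from 5 to 1 without array 1, hair follicle falls from 17 to 10 without array 3, and melanocyte falls from 6 to 3 without array 1 or 2 or dorsal control 2 or 3. Proliferation rises fell from 14 to 8 without array 2 and 6 without dorsal control 1, and tight junction falls from 6 to 3 without array 2. Macrophage rises fell from 5 to 3 without array 2 or dorsal control 2, alternatively activated macrophage rises from 4 to 2 without array 2 or 3 or dorsal control 2, and rises among genes raised in lesions from 10 to 6 without dorsal control 2.

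OXA-treated ears showed strong interferon and hyperplasia responses. Krt6b rose 85.7-fold over acetone-treated ears (log2 change 6.42 ± 0.08, SE, n = 3 and 3), the interferon-induced chemokines Cxcl9 and Cxcl10 76.6-fold (6.26 ± 0.15) and 67.3-fold (6.07 ± 0.12). Further rises were the chitinase-like Chil4 61.3-fold (5.94 ± 0.25), Stfa2 58.7-fold (5.88 ± 0.22) and the interferon-induced GTPase Iigp1 39.3-fold (5.30 ± 0.08). Krt24 fell 21.7-fold (-4.44 ± 0.21), the secretoglobin Scgb1a1 7.39-fold, Serpina3b 7.02-fold, Paqr7 5.89-fold, Ces1d 4.77-fold and Fmo2 4.76-fold. In total 1643 genes rose and 1798 fell, 472 and 114 of them at least 2-fold. The groups were fully apart for 35.2% of genes, where chance gives 10%. Flg and Il22 are not in the named genes of this table.

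Th1 and interferon genes rose in 18 of 22 (18 adjusted over the list alone), with a median log2 change of 1.98. Ifng rose 4.19-fold (2.07 ± 0.17), Cxcl11 39.3-fold and Ifit1 13.9-fold. NK and cytotoxic genes rose in 5 of 11 (5), including the granzymes Gzmb (5.71-fold) and Gzma (3.38-fold). IL-22, antimicrobial and hyperplasia genes rose in 18 of 20 (19), including S100a9 (27.8-fold) and S100a8 (25.5-fold), and genes raised in human lesions in 22 of 30 (23). Alternatively activated macrophage genes rose in 9 of 11 and 1 fell, Retnla (9 and 1), with Pdcd1lg2 at 2.54-fold beside Chil4. These 5 lists had camera adjusted p from 1.50e-22 (interferon) to 1.67e-05 (NK), and each had adjusted p = 0.0633 with an estimated correlation, the lowest of this comparison.

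Th17 and neutrophil-recruiting genes rose in 12 of 21 (13 rises and 1 fall adjusted over the list alone), with Il19 at 19.9-fold, Il1b at 11.3-fold, Cxcl2 at 9.62-fold and Il6 at 7.88-fold (camera adjusted p = 2.04e-09; adjusted p = 0.0839 with an estimated correlation). Il17a was at 5.83 ± 0.04 against 5.87 ± 0.03 (SD). Type 2 genes rose in 7 of 22 (8 rises and 1 fall). These were Ccl8 (11.1-fold), Il4ra (3.15-fold), Ccl11, Il13 (2.21-fold, 1.15 ± 0.19), Il33 (1.91-fold), Il13ra1 and Il4 (1.27-fold, 0.34 ± 0.09), with camera adjusted p = 0.00279 and adjusted p = 0.118 with an estimated correlation. Neutrophil genes gave 9 rises, such as Stfa2 and Cxcr2 (4.40-fold), and 2 falls, Mpo and Il1r2, among 17 (11 and 2; camera adjusted p = 3.11e-05; adjusted p = 0.148 with an estimated correlation). Mast cell genes gave 9 rises, such as Hdc (4.77-fold) and Tpsab1 (3.90-fold), and 1 fall, Mrgprb2, among 13 (11 and 1; camera adjusted p = 4.72e-08; adjusted p = 0.124 with an estimated correlation). Basophil genes rose in 3 of 7, Fcer1a, Mcpt8 and Il4 (3; camera adjusted p = 0.00584; adjusted p = 0.117 with an estimated correlation). Fcer1a and Mcpt8 were dim in both groups and Il4 in the acetone controls (5.40, cut at 5.41), so these rises are uncertain. T cell genes rose in 7 of 18 (10), such as Ctla4 and Icos (2.23-fold and 2.22-fold; camera adjusted p = 5.73e-06; adjusted p = 0.108 with an estimated correlation). Macrophage genes rose in 8 of 16 (9 rises and 1 fall), such as Clec7a (3.53-fold). Dendritic cell genes gave 6 rises, such as Fscn1, and 1 fall, the Langerhans cell lectin Cd207 at 2.24-fold, among 18 (7 and 1). These lists had camera adjusted p = 1.59e-06 and 0.00339, and adjusted p = 0.239 for both with an estimated correlation. No B cell or eosinophil gene passed.

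Hair follicle genes rose in 23 of 25 (23 adjusted over the list alone), with a median log2 change of 2.01 and Krt25 and Krt71 at 15.7-fold and 15.2-fold (camera adjusted p = 2.25e-22; adjusted p = 0.117 with an estimated correlation). Melanocyte genes fell in 4 of 10 (6), including Pmel at 1.89-fold (camera adjusted p = 0.00200; adjusted p = 0.179 with an estimated correlation). Sebaceous genes fell in 11 of 16 (11), led by Mc5r (2.32-fold) and Cidea (2.19-fold), with camera adjusted p = 2.25e-08 and adjusted p = 0.0839 with an estimated correlation. Muscle genes fell in 13 of 22 (16), such as Casq1 (2.44-fold), and adipocyte genes in 2 of 13, Plin4 and Car3 (9), with camera adjusted p = 3.60e-08 and 0.00214 and adjusted p = 0.276 and 0.325 with an estimated correlation. Cornified envelope genes gave 17 rises, such as Rptn (28.1-fold) and Lce3f (10.6-fold), and 8 falls, such as Flg2 and Krt77, among 35 (18 and 9; camera adjusted p = 0.000257; adjusted p = 0.118 with an estimated correlation). Collagen and matrix genes rose in 13 of 19 (18), such as Timp1 (7.72-fold) and Col1a1 (3.23-fold). Immediate early genes rose in 12 of 20 (12 rises and 1 fall), such as Socs3 (4.42-fold) and Atf3 (3.00-fold). These lists had camera adjusted p = 6.62e-13 and 8.68e-06, and adjusted p = 0.153 for both with an estimated correlation. Proliferation genes rose in 11 of 22 (12), such as Rrm2 (2.17-fold; camera adjusted p = 4.87e-09; adjusted p = 0.124 with an estimated correlation). Genes lowered in human lesions gave 1 rise, Fads2, and 7 falls, such as Cidea and Flg2, among 24 (2 and 11; camera adjusted p = 0.000770; adjusted p = 0.0839 with an estimated correlation). Tight junction genes gave 1 rise, F11r, and 5 falls, led by Cgn (1.90-fold), among 16, and barrier lipid genes 6 rises, led by Degs2 (5.97-fold), and 9 falls among 29. Cartilage genes gave 4 falls, led by Chad, among 15, and trunk Hox genes no call, and these 4 lists did not pass. Calls of Ccl11 (adjusted p = 0.122 without acetone control 3), Il4 (0.110 without OXA array 3) and Retnla (0.136 without OXA array 1) were lost on leaving out a single array. Muscle falls fell from 13 to 8 without acetone control 1 and cornified envelope falls from 8 to 5 without acetone control 3. Dendritic cell rises fell from 6 to 3 without OXA array 1 or 2, melanocyte falls from 4 to 2 without OXA array 1 or 3, and tight junction falls from 5 to 3 without OXA array 1 or acetone control 3.

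**Figure D4:**
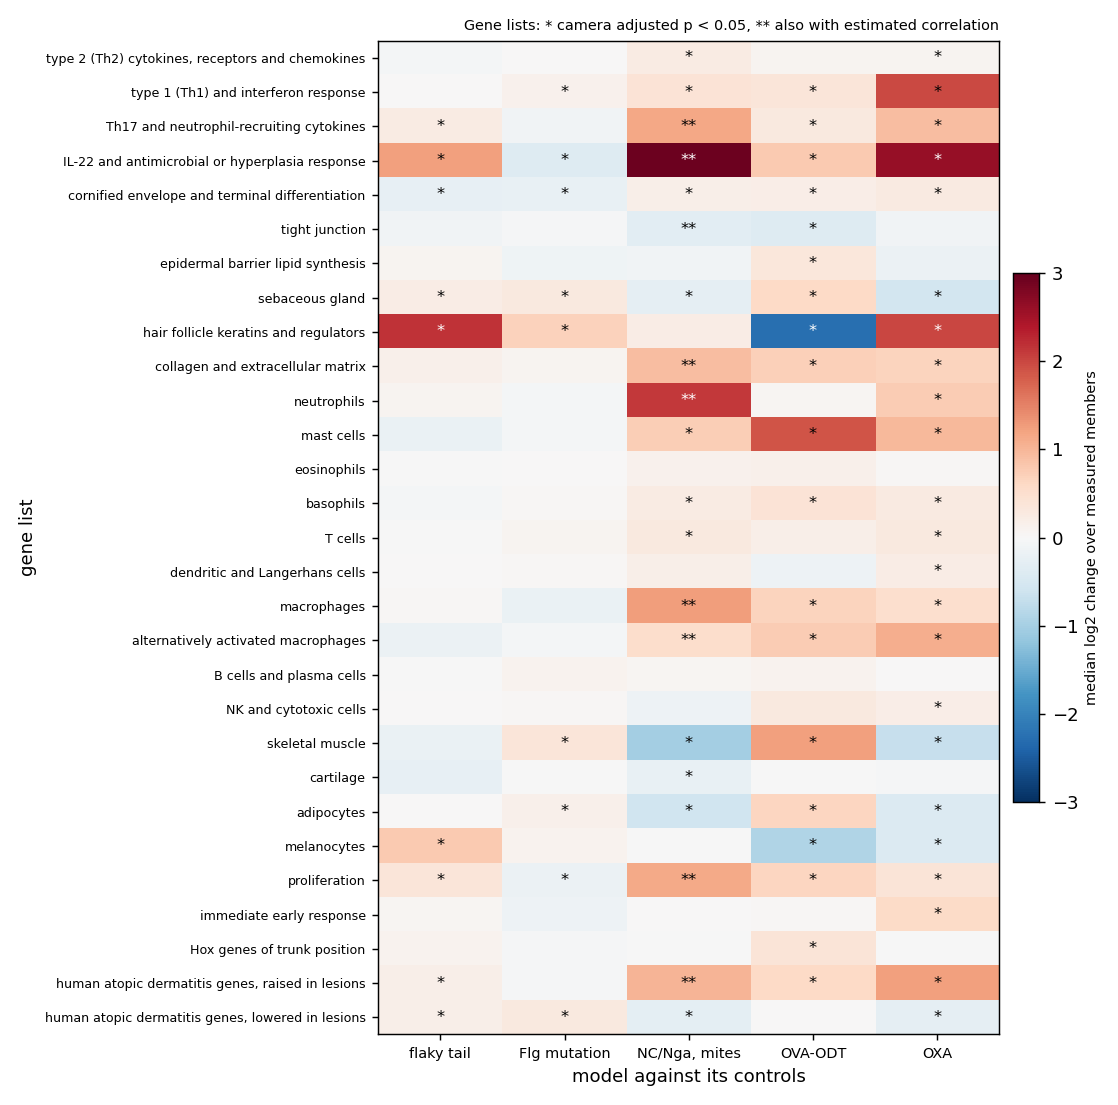
Median log2 change of the measured members of each gene list (vertical axis) in each model against its controls (horizontal axis), with 1 star for camera adjusted p under 0.05 and 2 stars where the list also passed with an estimated correlation. The IL-22 and antimicrobial list had medians of 2.95 in NC/Nga mice and -0.40 with the Flg mutation.

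Differences between models in the 31-array table were tested as differences of effects, each model against its own controls. Flaky tail and NC/Nga mice differed for 1303 genes, flaky tail and OVA-ODT for 1213, and the Flg mutation and NC/Nga mice for 2913. The Flg mutation and OVA-ODT differed for 1674, and NC/Nga mice and OVA-ODT for 1405. The change of Flg was lower in flaky tail than in NC/Nga mice by -2.27 ± 0.23 on the log2 scale and lower with the Flg mutation by -3.24 ± 0.23. Krt16 changed less in flaky tail than in NC/Nga mice (-3.51 ± 0.61), while S100a8 and S100a9 did not pass this test (-0.37 ± 0.67 and -0.26 ± 0.59). Neutrophil genes changed less in flaky tail than in NC/Nga mice, with a median difference of -1.83 and 9 of 18 genes lower (11 adjusted over the list alone; adjusted p = 0.0376 with an estimated correlation), Trem1 by -3.88 ± 0.56 and Clec4e by -3.76 ± 0.68. The same direction held for macrophage genes (median -1.29, 11 of 16 lower; 0.0167), such as Cd14 (-2.72 ± 0.53), and for collagen and matrix genes (median -0.64, 8 of 19 lower; 0.0167), such as Timp1 (-2.77 ± 0.49).

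Against OVA-ODT, flaky tail differed most in hair follicle genes, with all 26 higher and a median difference of 4.78 (adjusted p = 0.0259 with an estimated correlation), Krt84 by 5.86 ± 0.79 among them. Mast cell genes were lower for 8 of 14 (median -1.98; adjusted p = 0.00916 with an estimated correlation), including Cpa3 (-2.77 ± 0.40) and Mcpt4 (-2.02 ± 0.33). The change of Ifng was lower in flaky tail than with OVA-ODT by -1.23 ± 0.22, with the Flg mutation by -0.98 ± 0.22 and in NC/Nga mice by -1.06 ± 0.22. NC/Nga mice differed from OVA-ODT in Il1b (4.12 ± 0.89), Trem1 (4.18 ± 0.65), Il33 (1.20 ± 0.36) and S100a8 (3.13 ± 0.78), higher with mites, and in Cpa3 (-1.82 ± 0.40), Elovl3 (-1.93 ± 0.19) and Lpl (-1.70 ± 0.20), lower. No list of that pair passed with an estimated correlation.

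Across genes the log2 changes of flaky tail and NC/Nga mice correlated at 0.335 (Spearman 0.304) and those of NC/Nga mice and OVA-ODT at 0.286 (0.267), with 256 and 600 shared rises where independent lists would share 67.4 and 147. These pairs also shared 419 and 358 falls (83.0 and 89.7 if independent), and 71 and 154 calls were opposite (152 and 232). Flaky tail and OVA-ODT gave -0.017 (Spearman 0.198), yet shared 243 rises and 239 falls (51.0 and 45.7 if independent), with 133 opposite calls (103). The Flg mutation and NC/Nga mice gave -0.067 (-0.024), and the Flg mutation and OVA-ODT -0.030 (0.102). Of the 18962 genes measured on both arrays, 74 rose in flaky tail, NC/Nga mice, OVA-ODT and OXA alike, against 0.468 if the lists were independent, and these included Stfa3, Serpinb3a, Lcn2, Il1f6, Degs2, Krt1 and Casp14. In the same models 101 genes fell, against 0.391 if independent, including Paqr7, Cgn, Tgm7 and Mrgprb2. These expected counts take all genes as equally likely to be called. Models of the larger table share a fit and its spread per gene, so genes of low spread can pass more easily in each of them. The excess can therefore not be read as a shared response alone.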

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

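The tests of the sampled site, of sampling depth, of the shared controls and of Nnt were chosen after the result was seen, while those of hair follicle numbers, of donor DNA and of other splits were set before it. The readings of the hair follicle, donor DNA, sampling depth and Nnt tests were made stricter after their values were seen.

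Flaky tail arrays were labelled back skin, yet most genes that separate the sites lay near ear skin, though hair follicle and melanocyte list scores (8.15 and 5.59) lay between ear (6.03 and 4.76) and dorsal controls (9.59 and 6.29). If the RNA came from back skin, genes that separate dorsal from ear controls should lie near the dorsal level, and the median position of 0.123 between ear (0) and dorsal (1), with an upper quartile of 0.423, argues against that. On the same scale the Flg mutation was at -0.003, NC/Nga mice with mites at 0.205, and OVA-ODT, labelled dorsal, at 0.644. The muscle list score was 9.37 in flaky tail, 9.54 in ear controls and 4.62 in dorsal controls. Trunk Hox genes were at the ear level too (Hoxa5 3.11 in flaky tail, 2.75 in ear and 5.70 in dorsal controls), and the word back also stands in the genotype label, where it may mean a backcross, which was not tested, nor was an effect of the genotype on site genes.

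Hair follicle genes rose in flaky tail and OXA and fell with OVA-ODT, and all 26 differed between flaky tail and OVA-ODT (median difference 4.78). Deeper or shallower sampling should move adipocyte and muscle genes with them, but with OXA the adipocyte median was -0.41 and muscle fell too (-0.69), each with all 3 arrays below all 3 controls, though neither list passed with an estimated correlation (adjusted p = 0.325 and 0.276), which argues against depth there. Depth stays open in flaky tail (adipocyte median 0.021) and with OVA-ODT (0.65), where muscle (1.24) rose mainly on array 3 (0.19 without it) and both lists overlapped the controls. Different numbers of growing follicles might also be the source. Hair follicle and melanocyte scores correlated at r = 0.195 over 21 arrays with group means removed (interval -0.315 to 0.618, permutation p = 0.366). Spearman rho was 0.177 (permutation p = 0.450), r was 0.177 without the 2 farthest arrays, and the adjusted permutation p over 5 relations was 0.573. The r lies just under the bound of 0.2 set beforehand against this source, but with an interval too wide to decide. Between groups the picture was mixed. Melanocyte genes rose with hair follicle genes in flaky tail (7 of 10) and fell with them with OVA-ODT (6 of 10). With OXA melanocyte genes fell (4 of 10) as hair follicle genes rose. Effects of genotype, treatment and the hair cycle at each age were not tested and stay open.

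Flaky tail and the Flg mutation shared calls against the same ear controls. With the controls split between the comparisons the covariance of changes was 0.015, above the highest of 100 regroupings at 0.0116, which argues against chance values of the shared controls as the whole source, although the covariance with shared controls, 0.0314, lay within the simulated range (up to 0.0344). Nnt, which differs between C57BL/6 substrains, changed by -1.15 in flaky tail and -0.85 with the Flg mutation, but only the ear controls were high (7.69) and dorsal controls of the same label were at 6.88. Dorsal and ear controls also differ in site and age, so whether Nnt marks the substrain here cannot be told and substrain DNA stays open. DNA of a donor strain around Flg could add calls: 24 of 146 neighbours were called in flaky tail against 7.18% of other genes (odds ratio 2.54, past the bound of 2 set beforehand, interval 1.57 to 3.98, Fisher exact adjusted p = 0.000581), but the odds ratio was 1.63 (0.761 to 3.1) with the Flg mutation and 1.75 (1.18 to 2.55) in NC/Nga mice, where both groups are of 1 strain. The neighbours H2bc21, Riiad1, Lysmd1, Il6ra, Zfp687, Tars2 and Pip5k1a fell in both models, while Gm10685, Polr3gl and Cers2 were called with the Flg mutation but not in flaky tail. Il6ra and Lysmd1 also fell in NC/Nga mice, with OVA-ODT and with OXA, so donor DNA stays open. An effect of the filaggrin defect itself was not tested apart from these.

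Other splits of the arrays were counted for each number of called genes. In flaky tail 2 of 100 splits gave as many, the real one with 1689 and another with 1702. That share lies under 0.05, but the other split joined flaky tail arrays 1, 3 and 4 with ear controls 2 and 5 and gave more genes. It points to a structure of the samples that crosses the groups, so the count alone does not tie the 1689 genes to the model. With the Flg mutation 1 of 100 splits gave as many (974, highest other 2). In NC/Nga mice 1 of 100 did (3975, highest other 1272, from exchanging array 5 of each group). In flaky tail against the Flg mutation it was 1 of 100 (1559, highest other 104). These shares lie under 0.05, which argues against chance if the arrays are independent samples, but the labels do not say that they are. The 10 splits with OVA-ODT (2617; highest other 61) and with OXA (3441; highest other 0) are too few for a share under 0.05.

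Effects of the models differed from each other by tests of the difference itself. Flaky tail and NC/Nga mice differed for 1303 genes (highest other split 0), flaky tail and OVA-ODT for 1213 (0), the Flg mutation and NC/Nga mice for 2913 (1), the Flg mutation and OVA-ODT for 1674 (0), and NC/Nga mice and OVA-ODT for 1405 (180). The real split alone reached its count in each, 1 of 100 in the comparisons of flaky tail and of the Flg mutation with NC/Nga mice and 1 of 56 in those with OVA-ODT. Only arrays of the models were exchanged, after the mean of their own controls was subtracted, and the control arrays stayed fixed. Chance values of the controls therefore stay with the real split, so these splits cannot exclude chance for a difference of effects. Flaky tail differed from the Flg mutation itself for 1559 genes. Among lists, the effect in flaky tail was lower than in NC/Nga mice for neutrophils (median -1.83), macrophages (-1.29) and the IL-22 and antimicrobial list (-1.06), and against OVA-ODT lower for mast cells (-1.98) and higher for melanocytes (1.77). The effect of the Flg mutation was lower than in NC/Nga mice for the IL-22 and antimicrobial list (-3.37), neutrophils (-2.29) and macrophages (-1.37), and lower than with OVA-ODT for mast cells (-1.84), proliferation (-0.83) and basophils (-0.47).

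A single array lay far from the others of its group in 11 of 240 groups of gene or list values tested, where chance gives about 1 in 20, or 12. Flg mutation array 3 was highest for Ccl17 (7.26), Th2 genes (5.68), cornified envelope genes (9.00) and neutrophils (4.41), and array 4 for Cxcl10 (6.34). Flaky tail array 4 was lowest for Il33 (7.15) and Cldn1 (10.7), and array 5 for S100a8 (7.69). NC/Nga array 5 without mites was highest for Krt16 (8.51, others up to 6.02) and neutrophils (4.58), and array 4 for sebaceous genes (9.49).

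Probe sets without a single gene symbol lay outside the comparisons and were tested separately. Of 17824 such probe sets 369 changed in flaky tail, 184 with the Flg mutation, 828 in NC/Nga mice and 562 with OVA-ODT (2.07%, 1.03%, 4.65% and 3.15%, against 5.79%, 2.73%, 14.7% and 8.92% of named ones). With OXA 497 of 13120 changed (3.79%, against 10.1%).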

How the results depend on the processing

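The alternatives in this part were set before the data were examined, except 3 settings chosen after seeing the data, the omission of flaky tail array 4 with ear control 2, of OVA-ODT array 3, and of each array for the lists. Counts of called genes stayed within 1.5 times for all 11 comparisons and differences with trend and robust variance, for all 17 counts and correlations without the dimmest 25% of genes, and for the 6 comparisons with mean probe sets. With every probe set alone the number called also lay within 1.5 times for the 6 comparisons. It counts probe sets out of 41345 or 34760, not genes out of 22180 or 19937, so the units are unlike and the share called was lower. Further quantile normalization changed almost nothing (2618 in place of 2617 genes with OVA-ODT), since the values were already normalized, and is no test. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, counts fell to 814 in flaky tail, 420 with the Flg mutation and 1238 with OVA-ODT and held in NC/Nga mice and in flaky tail against the Flg mutation, while for OXA it is the same fit and no test. Dorsal in place of ear controls, which changes both site and age (15 in place of 26 weeks), gave 5327 in flaky tail; the cause was not tested. Array weights raised the Flg mutation count to 1550 and that of flaky tail against the Flg mutation from 1559 to 2287, while the other 4 also stayed within 1.5 times; the cause was not tested. The correlation of flaky tail and Flg mutation changes fell from 0.417 to 0.174 with split controls, which removes the shared arrays. Leaving out each array gave 1253 to 1775 genes in flaky tail, 437 to 1203 with the Flg mutation, 2950 to 4087 in NC/Nga mice, 1689 to 2246 with OVA-ODT, 2381 to 3257 with OXA and 829 to 1690 in flaky tail against the Flg mutation. Counts moved over 1.5 times for the Flg mutation without ear controls 2 (437) and 5 (526) and Flg mutation arrays 2 (593), 4 (450) and 5 (496). They did so for OVA-ODT without array 3 (1689) and dorsal control 1 (1743), and for flaky tail against the Flg mutation without flaky tail array 4 (906) and Flg mutation arrays 2 (945) and 5 (829); the cause was not tested beyond having fewer arrays. Without both flaky tail array 4 and ear control 2, flaky tail had 1469 genes, 1195 of them shared, and the Flg mutation 650. Of 544 results for named genes 472 were calls, and 100 of these were lost on leaving out some array; with only the compared groups 66 calls were lost and 6 gained, and no result reversed. Of 93 list calls 81 were lost with an estimated correlation and 12 kept, 7 were lost without the dimmest 25% and 1 with only the compared groups, and 15 on leaving out some array. Signal over background was not given, and dim genes limit what can be seen.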

Other observations

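Genes of the circadian clock changed in several models. These genes, and every test in this part, were chosen after values were seen, and the time of day of sampling is not given in the labels, so they are given as values. Of 9 measured genes of the output and repressor arm 8 fell in flaky tail (median log2 change -0.73, Ciart at -0.94 ± 0.16), 9 in NC/Nga mice with mites (-0.62, Hlf at -0.99 ± 0.15) and 1 with the Flg mutation (-0.13). With OXA 9 of 10 fell (-0.67, Bhlhe41 at -1.54 ± 0.14). Nfil3, a repressor that competes with Dbp, Tef and Hlf, rose in flaky tail (0.60), NC/Nga mice (1.12) and OXA (0.60). With OVA-ODT Dbp (1.24), Per3 (1.06) and Ciart (0.97) were higher and no output gene passed as lower, and Npas2 (-1.90), Nfil3 (-0.73) and Arntl (-0.66) fell. Npas2 also fell in NC/Nga mice (-0.75) and Arntl with OXA (-0.38).

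In NC/Nga mice the arrays numbered 5 lay nearest the other group for S100a8, though not for every gene. The mite array 5 had S100a8 at 5.98, where the other mite arrays had 8.01 to 9.34, and the no-mite array 5 had 4.70, where the others had 2.77 to 3.82.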
